A study of Mesomycoplasma hyopneumoniae with 6 samples.

How the data were processed

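Cultures of Mycoplasma hyopneumoniae, a bacterium of the pig respiratory tract, had been exposed to norepinephrine, a catecholamine stress hormone, or kept as controls. Per the series design text, 6 independent RNA samples of each condition were hybridised as pairs to 6 two-colour arrays. The replicate here is therefore the array with its pair of RNA samples. The dose and duration of the exposure are not given in the sources used here. The arrays lay on 3 slides, each with an upper and a lower array. Per the labels, RNA was prepared with a column kit with prolonged DNase treatment, and cDNA was labelled with Cy3 or Cy5 from primers chosen for the open reading frames of the species.

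The deposited values were intensity values on a linear scale. Per the file headers, each array file gave the mean of every spot and the median of its local background, for each dye in several scans of rising brightness. Per the labels, the authors quantified the scans with SoftWorx Tracker and then subtracted background, took natural logs, set the scans to a common median, applied LOWESS and averaged triplicate spots. None of those later steps is present in the deposited intensity columns. The table of processed values for the whole series held probe IDs with empty value cells, so an alternative from the authors' own normalized values was not run. Each array carried 2136 spots for 627 IDs; 547 IDs had 3 spots, 75 had 6 and 5 had 9. The files pair the IDs with no gene name, and no annotation was used here. IDs are therefore printed as the files give them, and the 20 gene lists and the genes fixed by name or symbol before the data were examined could not be measured.

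The dye orientation is recorded in conflicting ways. The channel labels put norepinephrine in Cy5 on 2 arrays and in Cy3 on 4, whereas the design text gives 3 arrays of each orientation. Before the data were examined, the channel labels were chosen for the primary fit, with a dye term because the orientations were then unequal in number. Turning each of the 4 arrays labelled norepinephrine in Cy3, one at a time, was fixed at the same time as an alternative.

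Signals were corrected per scan and dye with limma's normexp method and an offset of 50. Log2 signals of the scans of one array and dye were set to a common median and averaged. Cy5 over Cy3 log2 ratios were normalized within each array by global loess on all spots, and the spots of an ID were averaged. All spots carried IDs of one naming pattern, and none was marked as a control spot. Linear models with a dye term and a norepinephrine term were fitted to the 6 ratios of each ID with lmFit and eBayes (R 4.3.3, limma 3.58.1, statmod 1.5.0). Tests were two-sided, with Benjamini-Hochberg adjustment over the 627 IDs and a threshold of 0.05. A fold change is norepinephrine over control. Loess assumes that rises and falls balance at each brightness, so a shift of all transcripts together would not be seen.

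An ID was called dim in a channel if its mean spot signal in the first scan was under 1.5 times its background. No ID was dim in both channels on more than 3 arrays, or in all 6 channels of a condition, so the filter on dim IDs removed nothing and no fold change had to be given as a bound. Median signal in the first scan was between 7.06 and 21.1 times the median background over the 12 channels. The highest spot mean in any scan was 60104. Saturated single pixels would not show in a mean. The median standard error of a log2 fold change was 0.119 as labelled, 0.104 with the slide 2 lower array left out and 0.0917 with it turned. Precision therefore depended on how that array was treated, and not only on the number of arrays.

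The fit was tested on simulated ratios of all 627 IDs, drawn with the fitted dye effects and moderated residual spreads, in 20 runs with 200 of 627 IDs changed. With the labelled orientations, 85.8% of IDs simulated at a log2 change of 0.5 were recovered, and 99.8% at 1. With the slide 2 lower array turned, the corresponding values were 98.4% and 100%. False calls made up 3.74% and 3.19% of all calls. Every orientation was taken as right in the simulation, and the changed IDs were drawn at random. Recovery with the labelled orientations therefore does not cover an array that runs against the others. It does not show that changes of these sizes are absent as labelled. With no effect and no dye effect simulated, the highest number of calls in 20 runs with the turned orientation was 1.

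The rule for named IDs was the 12 largest rises and 12 largest falls among those past the threshold and of one sign on at least 5 of the 6 arrays. No ID passed as labelled, so the rule was applied to the fit with the slide 2 lower array turned, a choice made after the data were seen. Because the files pair no names with the IDs, only the first 2 per direction are printed, with 2 further IDs fixed beforehand by number. Alternatives covered background correction, normalization, spot averaging, the dye term, slide as a block, a separate-channel model, array weights, a trended and robust prior, each orientation, each array left out, and the threshold. Print-tip loess was not run because the files give no print blocks. Gene set tests were not run because no list could be built. Use of single scans, of IDs with 1 triplet of spots and of slides 1 and 3 alone was added after the data were seen.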

Results

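Mycoplasma hyopneumoniae is a bacterium of the pig respiratory tract. Its transcript levels were compared on 6 two-colour arrays between 6 RNA samples from cultures exposed to norepinephrine and 6 from control cultures. The comparison asks which transcripts respond to a host stress hormone. Each array measured 627 IDs on 2136 spots. The 2 arrays of slide 1 had 4 scans per dye, and the 4 arrays of slides 2 and 3 had 3. Median first-scan intensity ranged from 2747 to 5152 in Cy3 and from 1472 to 3309 in Cy5, over median backgrounds of 199 to 306 and 157 to 469. The standard deviation of the normalized log2 ratio across IDs was between 0.39 and 0.52 on the 6 arrays.

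The result of the comparison depended on the direction of 1 array. With the channel labels as given, no ID passed the threshold for a norepinephrine effect (limma, adjusted p at 0.05, n = 6 arrays). On slides 1 and 3, the labels put norepinephrine in Cy5 on the upper array and in Cy3 on the lower array. In these 4 arrays 65 IDs passed, but 3 with slide as a fixed block and 0 without the slide 1 lower or the slide 3 lower array. Each of these slides holds both orientations, so a slide term does not change the estimates. It leaves fewer residual degrees of freedom, as does leaving out an array. In the fit of slides 1 and 3 alone, an effect of array position cannot be separated from norepinephrine. The slide 2 arrays, given below, bear on it. Of the IDs named from the fit with the slide 2 lower array turned, mhp150 and mhp151 were lower with norepinephrine, with log2 fold changes of -1.67 ± 0.11 (SE) and -1.72 ± 0.13. mhp092 and mhp480 were higher, with 1.16 ± 0.17 and 1.00 ± 0.14. They were not the 2 extremes in each direction there: another ID, not named here, was at -1.98 ± 0.12, and another at 1.01 ± 0.14. What these IDs encode is not paired with them in the files.

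As labelled over all 6 arrays, 77 IDs had an unadjusted p under 0.05, where 31.4 would be expected by chance. The lowest adjusted p was 0.0521, for an ID with a log2 fold change of -1.69 ± 0.23 whose dye-corrected ratio was negative on 6 of 6 arrays. A separate-channel fit called 1 ID, and a fit that gave discordant arrays less weight called 64. The labelled log2 fold changes of the named IDs were -1.29 ± 0.41 for mhp150, -1.36 ± 0.38 for mhp151, 0.81 ± 0.37 for mhp092 and 0.75 ± 0.30 for mhp480, with adjusted p between 0.289 and 0.404. Each had its fitted sign on 5 of 6 arrays.

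The array that went against the others was the lower one on slide 2, labelled norepinephrine in Cy3. Its Cy5 over Cy3 log2 ratios correlated negatively across IDs with the other 3 arrays of that label (r between -0.502 and -0.285) and positively with the 2 arrays labelled norepinephrine in Cy5 (r = 0.550 and 0.587). The other 3 arrays labelled norepinephrine in Cy3 correlated among themselves at 0.673 to 0.742, and the 2 labelled norepinephrine in Cy5 at 0.546. IDs are not independent replicates. Turning the slide 2 lower array gives the 3 arrays per orientation that the design text states, but so would turning any of the other 3 arrays labelled norepinephrine in Cy3. The records therefore do not settle the direction of this array, and the comparison is given below with it left out and with it turned.

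**Figure D1:**
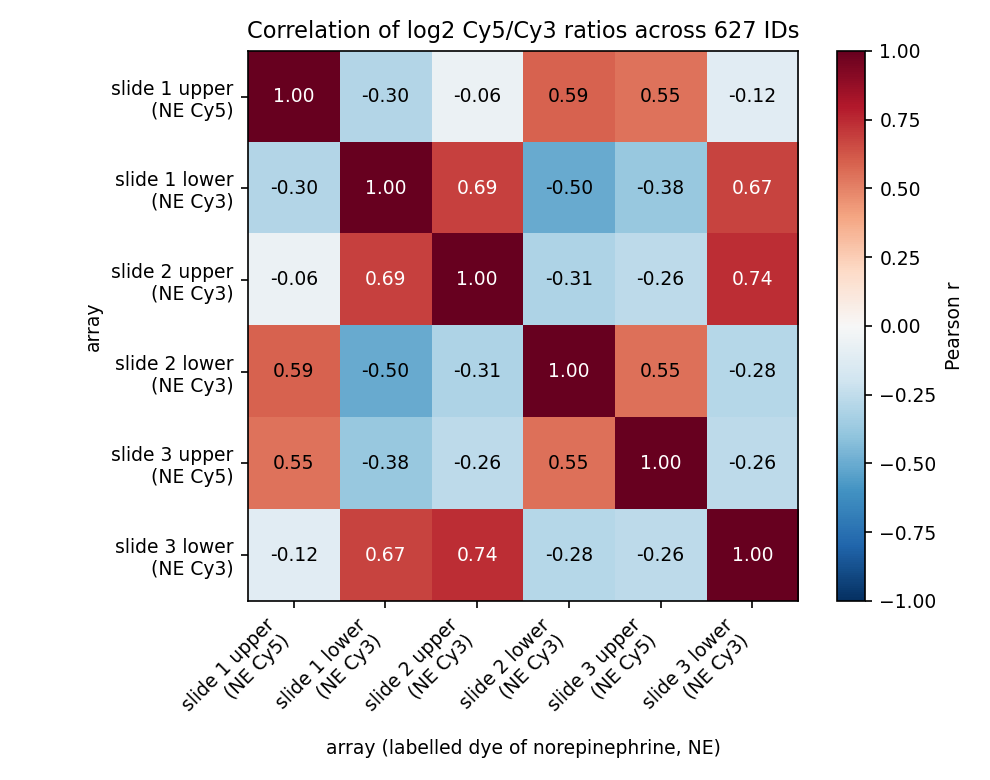
Pearson correlation across 627 IDs of the normalized log2 Cy5 over Cy3 ratio between each pair of the 6 arrays; axis labels give the array and the labelled dye of norepinephrine (NE), and the colour scale runs from -1 to 1. The slide 2 lower array correlates at 0.550 and 0.587 with the 2 arrays labelled NE in Cy5, and at -0.502 to -0.285 with those that share its own label.

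Of the 65 IDs that passed in slides 1 and 3, 29 were higher and 36 lower with norepinephrine. The effects measured on slide 1 and on slide 3 correlated at 0.660 across IDs. For slide 2, directions were read after the dye effect fitted in slides 1 and 3 was subtracted. On the slide 2 upper array as labelled, 61 of the 65 IDs (93.8%, exact Clopper-Pearson 95% interval 85.0 to 98.3) had the same direction. On the slide 2 lower array as labelled, 5 did (7.69%, interval 2.54 to 17.0). The intervals treat IDs as independent, which they are not. Both slide 2 arrays are labelled norepinephrine in Cy3. If array position had set the directions of the 65 IDs, few would match on slide 2 upper and most on slide 2 lower. With the positions as recorded, both slide 2 arrays showed the reverse, which argues against position as the main source of these directions. Without the slide 1 upper array the count of 65 was 114.

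With the slide 2 lower array left out, 100 IDs passed in the remaining 5 arrays, 47 higher and 53 lower. Of the 65 IDs of slides 1 and 3, 64 were among these 100, each with the same sign. The log2 fold changes were -1.67 for mhp150, -1.71 for mhp151, 1.13 for mhp092 and 1.02 for mhp480, with adjusted p between 1.67e-05 and 0.00128.

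When the slide 2 lower array was turned, 154 of 627 IDs (24.6%) passed the threshold, 82 higher and 72 lower with norepinephrine. The median size of a passing change was 1.35-fold, and the smallest was 0.24 on the log2 scale. There were 7 IDs that fell by at least 1 on the log2 scale and 3 that rose by as much. Of the 154 IDs, 94 also passed with that array left out and 64 also passed in slides 1 and 3, and all 154 had the same sign in these fits and as labelled. The fits share 4 to 6 arrays, so this overlap and sign agreement are in large part built in. The dye-corrected ratio had the fitted sign on all 6 arrays for 140 of them. Turning the slide 1 lower, slide 2 upper or slide 3 lower array instead gave 0 IDs each at the adjusted threshold in limma. At an unadjusted p under 0.05 these fits gave 9, 7 and 4 IDs, where 31.4 would be expected by chance. Counts so far under chance mark these fits as conservative, so their 0 is no neutral baseline for 154. Because the turned array was picked from 4 by its values, the count of 154 is not independent evidence of its orientation.

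The ranking of falls depended on the direction of the slide 2 lower array. In the turned fit mhp150 and mhp151 fell most, and the ID with the lowest adjusted p as labelled came next at -1.50 ± 0.27. That ID was the lowest in the other fits, at -1.69 as labelled, -1.88 with the array left out and -1.98 in slides 1 and 3. In the turned fit, mhp150 was lower by 3.06-fold (log2 fold change -1.61 ± 0.08 SE, adjusted p = 4.13e-06) and mhp151 by 3.02-fold (-1.60 ± 0.12, adjusted p = 3.70e-05). The largest rises in that fit were those of mhp092, at 2.28-fold (log2 fold change 1.19 ± 0.13, adjusted p = 0.000265), and mhp480, at 2.05-fold (1.04 ± 0.10, adjusted p = 0.000137). These 4 IDs had their fitted sign on 6 of 6 arrays. Within slide 1 alone their log2 ratios were -1.69, -1.90, 0.80 and 0.79 in this order, and within slide 3 alone -1.65, -1.55, 1.52 and 1.20. Of the 2 IDs fixed beforehand by number, mhp182 had a log2 fold change of -0.06 ± 0.11 (adjusted p = 0.695) and mhp183 of -0.22 ± 0.13 (adjusted p = 0.243). As labelled, their values were 0.05 ± 0.13 and -0.02 ± 0.17.

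**Figure D2:**
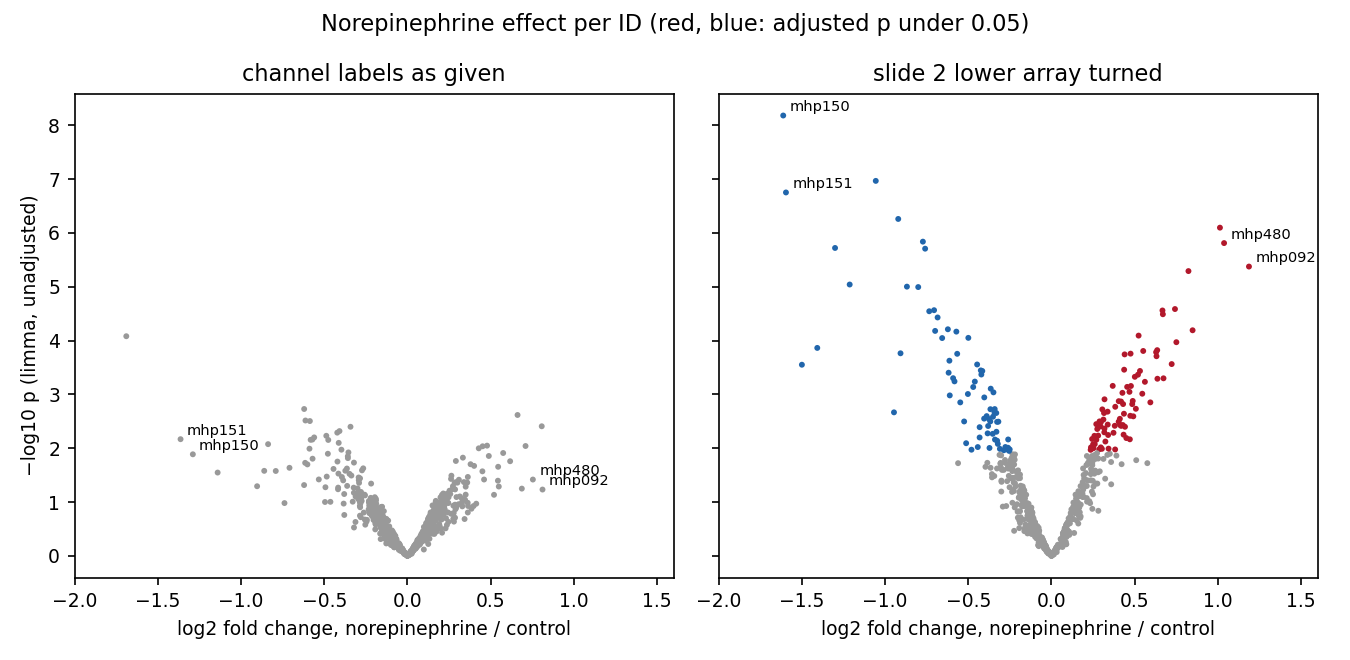
Each point is 1 of 627 IDs, with the log2 fold change (norepinephrine over control) on the horizontal axis and the −log10 of limma's unadjusted p on the vertical axis, for the channel labels as given (left) and with the slide 2 lower array turned (right). Red and blue points pass an adjusted p of 0.05: none on the left, and 82 higher and 72 lower on the right.

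**Figure D3:**
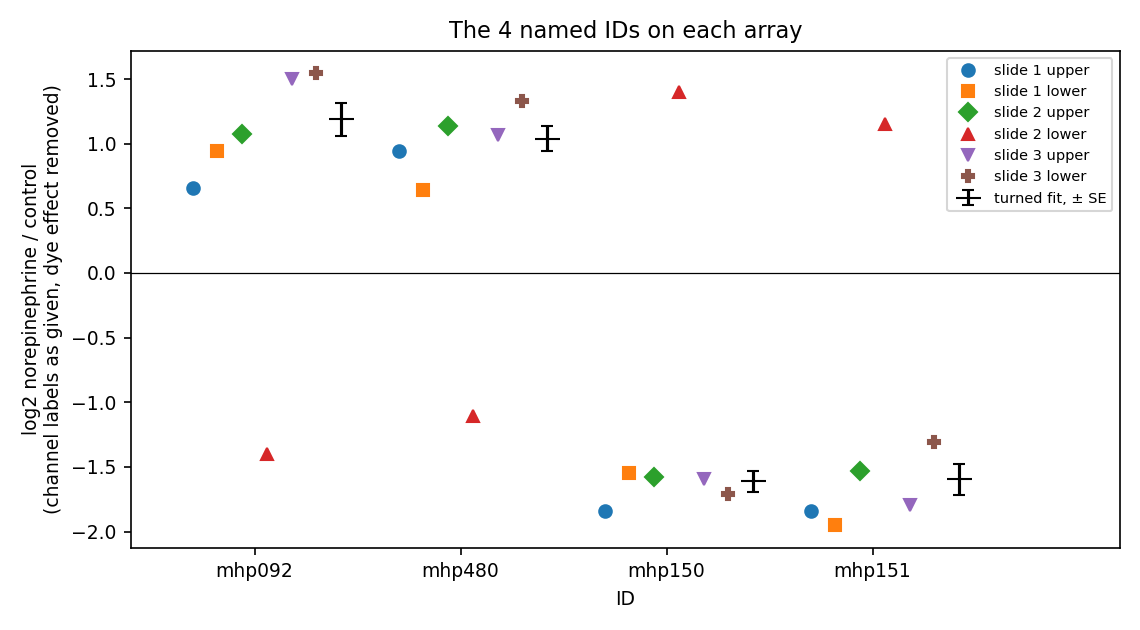
Log2 ratio of norepinephrine over control for the 4 named IDs on each of the 6 arrays, with the channel labels as given and the dye effect of the turned fit removed; black bars are the turned fit's estimate ± SE. For each ID, the slide 2 lower array lies on the opposite side of 0 from the other 5 arrays, which the choice of these IDs from the turned fit largely fixes.

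IDs that passed were often neighbours in number. In the turned fit, 35 of the 154 IDs lay in 7 runs of at least 3 consecutive numbers that passed in one direction, whereas 10000 shuffles of the calls among IDs gave a median of 6 and at most 25. The longest run held 10 consecutive IDs, all lower, and contained mhp150 and mhp151. Its log2 fold changes lay between -1.61 and -0.33 with a median of -1.13, and 6 of the 7 falls of at least 1 were in it. In slides 1 and 3 alone, 8 of its 10 IDs passed, with a median over the run of -1.10. The run around mhp480 held 6 consecutive IDs, all higher, with log2 fold changes between 0.63 and 1.04, and all 6 also passed in slides 1 and 3. Another run of 6 higher IDs had log2 fold changes between 0.30 and 0.59, and 1 of its IDs passed in slides 1 and 3. mhp092 had no passing neighbour of its direction.

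**Figure D4:**
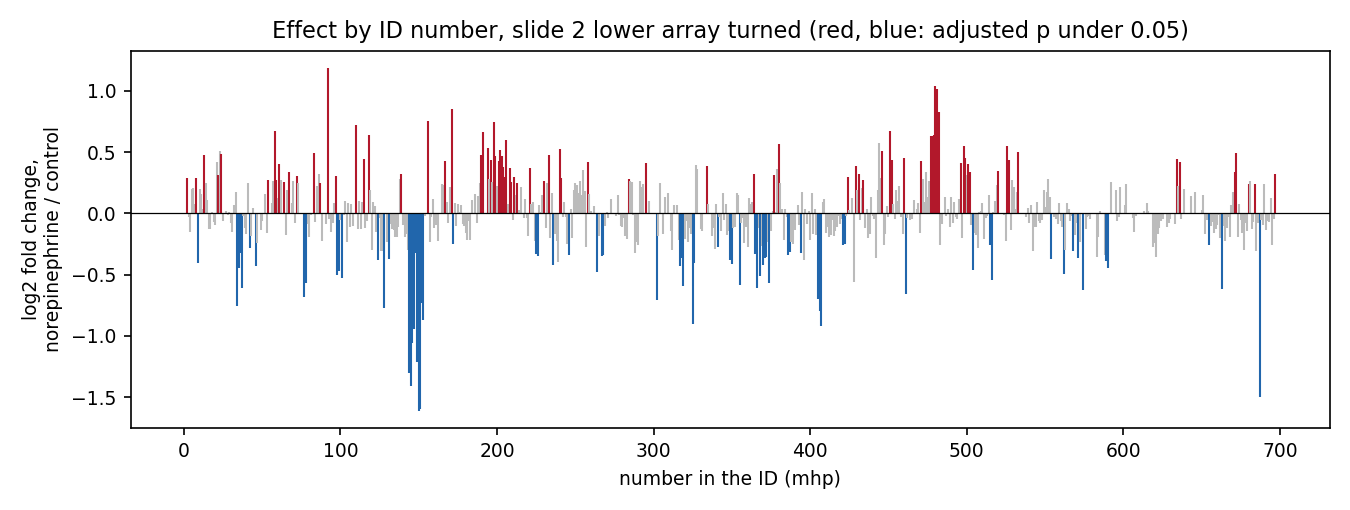
Log2 fold change (norepinephrine over control) of each ID against the number in its name, with the slide 2 lower array turned; red and blue mark an adjusted p under 0.05. The run of 10 lower IDs that contains mhp150 and the run of 6 higher IDs that contains mhp480 stand out.

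Passing IDs were found at all signal levels. In the low, middle and high tercile of mean signal, 40, 61 and 53 of 209 IDs passed in the turned fit, of which 19, 34 and 29 were higher.

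The dye effect, Cy5 over Cy3, was the technical background of the comparison. It passed the threshold for 12 IDs as labelled, 2 brighter in Cy5 and 10 in Cy3, and for 65 IDs in the turned fit, 15 brighter in Cy5 and 50 in Cy3. Both counts rested on single arrays: the 12 became 50 without the slide 2 lower array and 0 without any other one, and the 65 became 5 without slide 2 upper, 10 without slide 3 lower and 24 without slide 1 upper. For mhp092, mhp480, mhp150 and mhp151 it was between -0.69 and -0.42 on the log2 scale in the turned fit, smaller in size than their norepinephrine effects.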

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

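The tests that weigh an explanation in this part were chosen after the result was seen. A gap rule over the 4 arrays labelled norepinephrine in Cy3 was applied to 12 measures and singled out 2. Chance does so in about 1 in 20 where the 4 values are independent. This rate does not hold for the correlations, because each array also enters the means for the others. It also does not hold for the 4 measures on IDs picked from the fit with the slide 2 lower array turned. The rate therefore applies to neither of the 2 flagged measures. Both flagged measures concern the slide 2 lower array. Its ratio correlated at -0.396 with the mean of the other 3 arrays, against 0.522 to 0.698 for those 3. Its log2 ratio of mhp150 was 2.00 as labelled, against -1.11 to -0.94 on the other 3, which is partly built into the choice of this ID from the turned fit.

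The slide 2 lower array ran against the other 5 arrays. Dye bias of single probes would make the Cy5 over Cy3 ratios of all arrays more alike, whatever their label. An effect of the lower position would make the ratios of this array resemble those of the other lower arrays. The highest r was -0.285 both with the arrays of its label and with the other lower arrays. It came from the same pair of arrays, as the other lower arrays share its label. These negative r are part of the pattern itself, so they are no separate test of either explanation. Neither explanation alone would give their sign. Channels turned in the labels, or an exchange of its 2 RNA samples, may account for the pattern. With the dye effect of slides 1 and 3 subtracted, 92.3% of the IDs that passed there went the opposite way on the slide 2 lower array. This does not exclude turned channels or exchanged samples, but it restates the pattern and gives no support. A response of its cultures in the opposite direction was not tested. Turned labels and exchanged samples cannot be told apart, because each predicts the same turned ratios. An opposite response need not mirror the other arrays ID by ID, but one that did would give the same ratios too.

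As labelled the count was 0, which every split reaches whatever the data, so the 15 of 15 splits of the arrays into orientations of 2 and 4 that did so say nothing; the highest count in the other splits was 0. For the turned array, 1 of the 10 splits into 3 and 3 gave as many as 154, and the highest of the others was 0. These 10 splits are too few for a share under 0.05.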

How the results depend on the processing

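As labelled, the count of 0 IDs stayed at 0 in 16 of 27 alternatives. It was 1 with median centring, the median of spots, the last scan, slide as a fixed block, a trended and robust prior, the separate-channel fit and adjusted p at 0.10, 20 at an unadjusted p of 0.01, and 64 with array weights. Leaving out 1 array gave 0 to 100 (100 without slide 2 lower), and turning slide 2 lower gave 154. The labelled dye count of 12 became 1 with no background correction, 2 with the first and 7 with the last scan, 25 with slide as a random block and in the separate-channel fit, 34 with array weights, 0 to 50 with 1 array left out (50 without slide 2 lower, otherwise 0), and 0, 0, 65 and 2 with slide 1 lower, slide 2 upper, slide 2 lower and slide 3 lower turned. With slide 2 lower turned, the count of 154 lay between 108 and 212 in 19 of 23 alternatives and was 100 without slide 2 lower, 92 with the last scan, 91 without a dye term and 236 at adjusted p 0.10. The dye count of 65 was 35 with the last scan and 5 to 64 with 1 array left out (5 without slide 2 upper, 10 without slide 3 lower, 24 without slide 1 upper). In slides 1 and 3, the count of 65 became 31 with no background correction, 43 with median centring, 106 with the first and 25 with the last scan, 22 without a dye term, 3 with slide as a fixed block, 109 at adjusted p 0.10, and 0 to 114 with 1 array left out (0 without slide 1 lower or slide 3 lower, 114 without slide 1 upper). The cause was not tested. The 4 named IDs kept their sign in all alternatives to the turned fit, and their threshold in all that gave a test (highest adjusted p 0.0117). They were picked as extremes of that fit, which largely builds this in. As labelled, none of the 4 passed. Alternatives to the turned fit and to slides 1 and 3, and the single scans, were chosen after the data were seen. The filter on dim IDs removed no ID, so it tests nothing. Print-tip loess, the authors' processed values, gene lists, and slide as a random block in slides 1 and 3 were not run.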

Other observations

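All tests in this part were chosen after the data were seen. Effects of IDs with neighbouring numbers went together. In the turned fit, the log2 fold changes of IDs 1 number apart correlated at 0.483 over 580 pairs, against at most 0.161 in 10000 shuffles (one-sided permutation p = 1e-04, the smallest they can give). The correlation was 0.366 at a distance of 2, 0.20 at 5 and 0.0578 at 10, and at a distance of 1 it was 0.436 in slides 1 and 3 alone and 0.392 as labelled. Spots printed near each other could share local artifacts, but at a distance of 1 the residual ratios reached at most 0.140 on any array and the dye effect 0.163, which argues against this as the whole cause at that distance. The dye effect correlated at 0.207 at a distance of 5 and 0.129 at 10, no less than the norepinephrine effect, so it stays open there. Neighbouring genes that are transcribed together may account for the pattern, which cannot be told apart here because no transcript map was used and the files do not say that the numbers follow the genome.

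In 80 IDs the spots came in more than 1 triplet, and the triplets differed. On single spots, effects in the turned fit correlated at 0.678 on average inside a triplet and at 0.295 across the first 2 triplets of an ID, a difference of 0.383 (bootstrap 95% interval 0.207 to 0.555, 2000 draws over IDs). Mean signal correlated at 0.826 inside and -0.139 across triplets. Different DNA under one ID is a candidate explanation, and the mean over such an ID may then mix targets. The triplets had effects of opposite sign in 29 of the 80 IDs. Of the 80 IDs, 17 passed, 1 of them with opposite signs, but passing on the mean favours triplets of one sign.

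Effects varied less across IDs in the last scan than in the first. In the turned fit, the standard deviation of the log2 fold change was 0.375 in the first scan and 0.288 in the last over all IDs, and 0.285 and 0.278 in the low, 0.430 and 0.313 in the middle and 0.396 and 0.273 in the high tercile of mean signal. Neither the difference between scans nor that between terciles was tested. There were 186 IDs that passed in the first scan and 92 in the last, of which 80 were shared. The log2 fold change of mhp150 was -1.77 in the first scan and -1.46 in the last.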
